A study of Mus musculus with 6 samples.

How the data were processed

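Gene expression was measured on Affymetrix mouse arrays in whole pineal glands of newborn mice of strain 129 at postnatal day 0. There were 6 pools, 3 wildtype and 3 homozygous for the Neurod1 knockout, and each pool held 3 glands and was run on 1 array. Per the labels' protocols, the mice lived in 12 h of light and 12 h of dark, tissue was taken by day, the RNA went through a single amplification, and the amplified RNA was labelled with biotin for hybridisation. Each pool was a separate biological sampling per the series' design text, so the spread between pools of a group holds biological and technical variation.

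The values are the deposited table of probe set signals, a linear fluorescence intensity with 1 value for each of 45037 probe sets and 6 arrays. The GCOS software is named in the submitters' processing notes without a version, and the algorithm behind the signal is not given in the sources used here. In the deposited intensity columns the 2% trimmed means lay between 499.5 and 499.96, so each array had been scaled to a level of 500 before deposit, while medians lay between 132 and 184. Detection calls, control probe sets and scanner files were not analysed here, so RNA integrity and background could not be checked from them. No 2 arrays shared over 0.127% identical values.

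The values were used without further normalization, as log2(signal + 38.6), where the offset of 38.6 is the 20th percentile of all deposited values. A log2 difference on this scale understates the change of dim genes. Gene names came from the platform annotation supplied with the table: 34945 probe sets named 1 gene, 932 named several and 9160 named none. Gene identifiers of 34741 probe sets matched the RefSeq table of assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for the order of genes on their chromosomes. The 40% of probe sets with the lowest mean over the 6 arrays, which corresponds to a signal under 105, were left out. A gene was represented by its probe set of highest mean, which left 12797 of 18193 named genes for testing.

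Knockout was compared with wildtype in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a mean-variance trend, 4 residual degrees of freedom, a two-sided test and a Benjamini-Hochberg adjusted p under 0.05. Differences are knockout minus wildtype. Signals are given as mean ± SD over 3 pools and log2 differences with the standard error (SE) of the limma fit. With 3 pools against 3 an exact permutation test of 1 gene cannot go below p = 0.1, so no such test is given. The number of arrays limits the precision, and the median SE over genes was 0.34 on the log2 scale.

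Before the data were examined, 23 gene lists were fixed, covering pineal and photoreceptor functions, proliferation, neurons, the clock, stress, and cell types that a dissected gland could hold. Lists with at least 5 tested members were compared with all other tested genes by camera, with its preset correlation of 0.01 between genes and adjustment over the lists. The sex-linked list had 4 tested members and was not tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. Lists of spermatid, testis somatic, Y-linked, and ribosomal and respiratory chain genes were made after the data had been examined and are used only to describe single arrays.

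The rule for named genes was also fixed beforehand. It took Neurod1, then up to 14 genes with the largest fall and 14 with the largest rise among those past the threshold without overlap between the groups, then up to 4 members of each tested list with the smallest p, and always Tph1, Aanat, Asmt, Crx, Otx2 and Pax6. Where no gene passed in a direction, the 5 with the smallest unadjusted p were taken and are given as values. The rule named 95 genes. A further 5 with the smallest p among genes with lower values were added after their values were seen, which makes 100. Asmt was not analysed here.

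The labels give pools of the same number in both groups a shared date. Deviations from the group means correlated across genes by 0.32, 0.25 and 0.36 within numbers 1, 2 and 3, and by at most −0.04 between different numbers. The deviations of a group cancel out, so positive values within numbers force negative ones on average between numbers, which are not separate evidence. The labelled pairing had the highest mean correlation of the 6 possible, which chance alone gives in 1 of 6 cases. Given the shared dates and the correlations within numbers, pools were treated as paired by number in an alternative fit with the number as a block. Differences within each number are given for list shifts. The median SE over genes was 0.28 in the blocked fit, against 0.34 without the block. SEs printed with gene differences come from the fit without the block unless stated.

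Other alternatives changed the offset, the normalization between arrays, the filter, the choice of probe sets, the variance model and array weights, and left out each array in turn. Leaving out both pools numbered 1 or both numbered 2 was added after the data had been seen. The fitting and list tests were first tested on simulated data for this comparison, with 20 simulations of 12797 genes with independent noise, of which 200 were changed. Of genes changed by 1, 2, 3 and 4 on the log2 scale, 9.6%, 86%, 98.5% and 99.6% were recovered, and 5.40% of calls were false. So many changed genes ease the unadjusted p that a call needs. With 1 gene called in the real data a smaller p was needed, so these shares overstate what could be called here. A list of 36 genes shifted by 0.5 was recovered in 20 of 20 simulations, with the preset and with the estimated correlation, and an unchanged list was called in 1. These list counts used an unadjusted camera p under 0.05. Simulated list members were uncorrelated, while the estimated correlation in the real phototransduction list was 0.31. The counts therefore do not bear on how reliable the preset correlation is for the real lists. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.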

Results

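Transcript levels were measured in pineal glands of newborn 129 mice, either wildtype or homozygous for a knockout of Neurod1, which encodes a basic helix-loop-helix transcription factor of neurons, endocrine cells and photoreceptors. Each genotype had 3 pools of 3 glands, each run on 1 array. The comparison asks which pineal transcripts differ at birth in animals that lack this factor. After the authors' scaling, the median signal of an array lay between 132 and 184 and the 20th percentile between 28.4 and 45.6.

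Transcripts of other tissues differed between single pools in ways that the genotype did not order. Ttr, the transthyretin gene that is abundant in choroid plexus, had signals of 898 in wildtype pool 1 and 685 in knockout pool 3, against 38903 to 87464 in the other 4 pools. Crisp2, a gene of male germ cells, reached 17677 in knockout pool 2 and 1700 in wildtype pool 2, and lay between 3.2 and 11.2 elsewhere. The Y-linked gene Eif2s3y had signals of 22.5 in wildtype pool 2 and 75.2 in knockout pool 1, and between 1216 and 4278 in the others. Over 213 genes of ribosomal proteins and the respiratory chain, the median was 1.00 above the mean of the 6 arrays on the log2 scale in knockout pool 1, and lay between −0.60 and 0.13 in the remaining pools. These genes, outside the rule for named genes, were chosen after their values were seen.

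**Figure D1:**
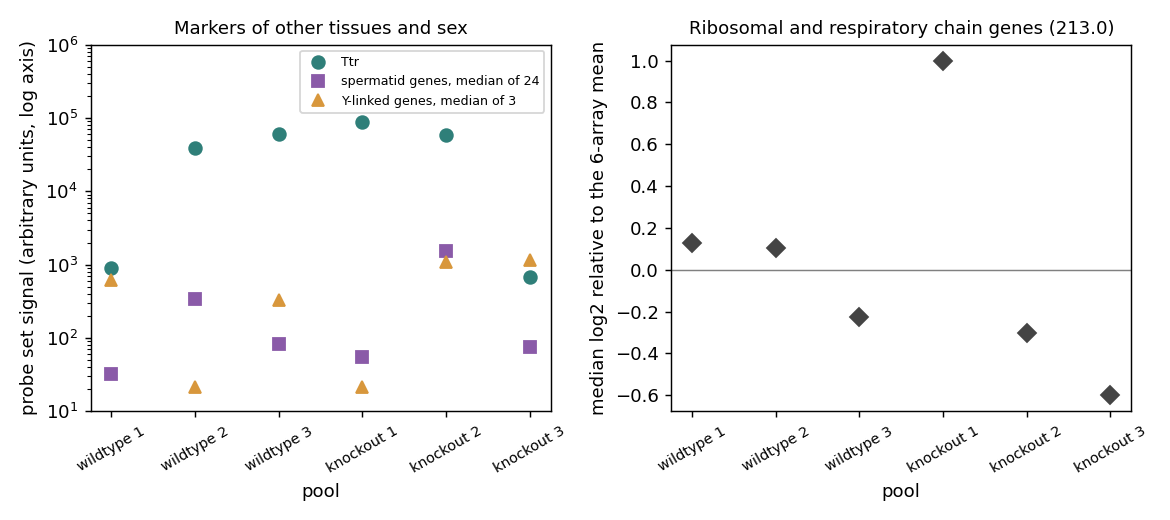
The left panel plots probe set signal in arbitrary units on a log axis for each of the 6 pools, with Ttr as circles, the median of 24 spermatid genes as squares and the median of 3 Y-linked genes as triangles, and the right panel plots the median log2 level of 213 ribosomal and respiratory chain genes relative to the mean of the 6 arrays. Ttr is lowest in wildtype pool 1 and knockout pool 3, the spermatid median reaches 338 and 1525 in the pools numbered 2, and knockout pool 1 stands highest in the right panel at 1.00.

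Neurod1 itself fell in the knockout pools. Its probe set 1426413_at had signals of 8616 ± 959 in wildtype and 346 ± 204 in knockout (SD, n = 3), a ratio of means of 24.9. The log2 difference was −4.67 (SE 0.45), with a limma adjusted p of 0.0362. Within pool numbers 1, 2 and 3 the difference was −4.40, −4.05 and −5.55. The second probe set, 1426412_at, gave 8157 ± 445 and 320 ± 248 (SD, n = 3) and a log2 difference of −4.73. Both probe sets separated every knockout pool from every wildtype pool, so the target gene followed the labels, although the labels do not say which part of the gene was removed. Leaving out 1 pool kept the log2 difference between −5.04 and −4.13. The adjusted p was then 0.621, 0.316 or 0.377 without wildtype pool 1, 2 or 3, 0.0985 without knockout pool 1, 0.0450 without knockout pool 2 and 0.00561 without knockout pool 3.

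**Figure D2:**
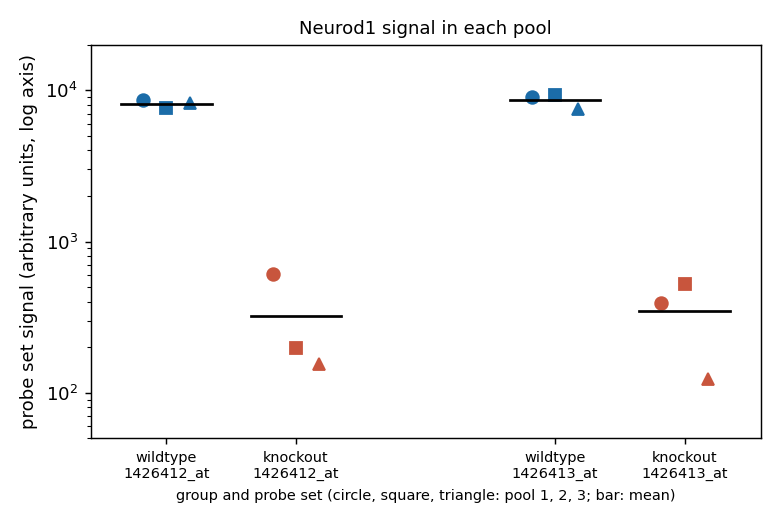
The plot shows the Neurod1 signal of each pool on a log axis in arbitrary units for both probe sets, with circles, squares and triangles for pools 1, 2 and 3 and a bar at the group mean. The wildtype pools lie between 7519 and 9301 and the knockout pools between 122.5 and 605.

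Among 12797 genes tested, Neurod1 was the 1 gene that was lower in knockout at an adjusted p under 0.05 in limma, and 0 genes were higher. At an unadjusted p under 0.05 there were 428 genes, 3.34% of those tested. With the replicate number as a block, Neurod1 was again the 1 gene called, while 798 genes, 6.24%, had an unadjusted p under 0.05. Chance gives 5% on average, but genes that vary together widen the spread of this share. In other splits of the 6 arrays, fitted without the block, the count ran from 108 to 2407 genes. Neither share is therefore read against 5%. The groups did not overlap for 1293 genes, 10.1% of those tested. Chance gives 10% for 6 exchangeable arrays, which these are not, since same-numbered pools share deviations, so the share is not read against it. The 5 genes with the smallest p among those with higher values were Hdc, Fbxw22, Pik3ip1, Epcam and Ubxn11, none past the threshold. The groups did not overlap for any of them, which alone makes each higher in knockout within all 3 pool numbers. Hdc, which encodes the histamine-forming enzyme histidine decarboxylase, had signals of 206 ± 70.5 in wildtype and 582 ± 120 in knockout (SD, n = 3), a log2 difference of 1.36 (SE 0.30). Pik3ip1, an inhibitor of phosphatidylinositol 3-kinase, had 277 ± 27.3 and 639 ± 108 (SD, n = 3). Fbxw22, an F-box gene, had 406 ± 17.4 and 866 ± 28.0, the epithelial adhesion gene Epcam 140 ± 41.6 and 402 ± 103, and Ubxn11 77.2 ± 24.6 and 259 ± 35.5 (SD, n = 3), with log2 differences of 1.38 and, for the other Ubxn11 probe set, 0.50. For every gene except Neurod1 the adjusted p was 0.998 or above. No offset before the logarithm ended the call of Neurod1 (adjusted p = 0.0683), and limma's array weights, which gave 7.05 and 6.20 to the pools numbered 2 and at most 0.541 to the rest, called 1512 higher and 1420 lower genes.

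None of the genes of melatonin synthesis and adrenergic control passed the threshold on its own. The list had 17 tested members, 13 with lower and 4 with higher means, and camera with its preset correlation called it lower (median log2 difference −0.18, adjusted p = 0.0242). With an estimated correlation its adjusted p was 0.411. Within numbers 1, 2 and 3 the median difference was −0.07, −0.26 and −0.27. Tph1, which encodes the tryptophan hydroxylase of the first step of serotonin synthesis, had signals of 10090.2 ± 4523 in wildtype and 6350.3 ± 5352 in knockout (SD, n = 3; log2 difference −0.89, SE 0.57). Knockout pool 1 had a Tph1 signal of 12501, against 3795 and 2755 in knockout pools 2 and 3, and the difference was −0.27, −1.22 and −1.18 within numbers 1, 2 and 3. It lay between −1.54 without knockout pool 1 and −0.45 without knockout pool 3. Aanat, the arylalkylamine N-acetyltransferase gene, had 453 ± 57.2 and 328 ± 85.6 (−0.45, SE 0.28, and −0.23 without knockout pool 3). Within numbers 1, 2 and 3 the Aanat difference was −0.04, −0.26 and −1.04. Ddc, the aromatic amino acid decarboxylase gene, had 3065 ± 1350.3 and 1495 ± 876 (−1.08, SE 0.46), and Prkar2b, a regulatory subunit gene of protein kinase A, 6758 ± 173 and 4246 ± 360 (−0.67, SE 0.28). The Ddc difference was −0.88, −1.08 and −1.28 within numbers 1, 2 and 3. With the number as a block its SE was 0.23 and its limma adjusted p 0.768. The call ended without wildtype pool 1 (adjusted p = 0.110), knockout pool 2 (0.0768) or knockout pool 3 (0.129), and with no filter on dim probe sets (0.0569).

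The phototransduction and photoreceptor list gave the lowest p of all lists in camera with the preset correlation, but not with an estimated correlation or in fry. Of its 36 tested members, 25 had lower and 11 had higher means in knockout, and camera with the preset correlation called the list lower (median −0.44, adjusted p = 0.00111). With an estimated correlation the adjusted p was 0.411. The shift was not shared by all pools: within numbers 1, 2 and 3 the median difference was 0.14, −0.46 and −0.48, and knockout pool 1, in which ribosomal transcripts stood high, had a list median of 0.40 relative to the 6 arrays, beside 0.44 in wildtype pool 1. Gnat2, the cone transducin alpha subunit gene, had signals of 795 ± 33.3 in wildtype and 422 ± 99.7 in knockout (SD, n = 3; log2 difference −0.88, SE 0.26). Cplx4, a complexin of ribbon synapses, had 2872 ± 150.3 and 1488 ± 188 (−0.94, SE 0.27), and the kinase gene Mak 310 ± 34.1 and 192 ± 24.9 (−0.60, SE 0.26). Abca4, the retinoid transporter gene, had 1713 ± 111 and 1043 ± 997 (−1.07, SE 0.54), with differences of 0.44, −1.79 and −1.88 within the 3 numbers, −1.79 without knockout pool 1 and −0.71 without knockout pool 2. Leaving out knockout pool 3 ended the call (adjusted p = 0.0827).

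Transcription factors of pineal and photoreceptor cells had 16 lower and 10 higher means among 26 tested. Camera gave this list an adjusted p of 0.0525, with a median of −0.09, and 0.346 with an estimated correlation. With the replicate number as a block it was called lower with the preset correlation, at an adjusted p of 0.0465, and not with an estimated one in the same blocked fit (adjusted p = 0.452). The blocked fit has few residual degrees of freedom, so the latter decides little. The median differences within numbers were −0.12, −0.25 and −0.46. With the preset correlation the list was also called lower without wildtype pool 1 (adjusted p = 0.0141) or wildtype pool 2 (0.0460), with quantile normalization (0.0318) and with no filter (0.0405). The same held without both pools numbered 1 (0.0263), an alternative chosen after seeing the data. St18 had signals of 526 ± 129 and 257 ± 88.3 in wildtype and knockout (SD, n = 3; log2 difference −0.96, SE 0.32), Rxrg, a retinoid X receptor gene, 508 ± 224 and 239.5 ± 127 (−0.99, SE 0.40), and the zinc finger gene Insm1 2474 ± 505 and 1356 ± 624 (−0.92, SE 0.38, with −0.49 for its other probe set). The homeobox genes Crx, Otx2 and Pax6 had log2 differences of −0.44 (SE 0.49), −0.40 (SE 0.28) and −0.59 (SE 0.31). Their signals were 3983 ± 1680.4, 14034 ± 1199 and 1330 ± 272 in wildtype, against 3170 ± 2082, 10652 ± 1324 and 878 ± 235 in knockout (SD, n = 3). Crx was high in both pools numbered 1, at 5902 in wildtype and 5549 in knockout. Within numbers 1, 2 and 3 its difference was −0.09, −0.52 and −0.71, and with the number as a block its SE was 0.25 (limma adjusted p 0.768). In the fit without the block, the Crx difference was −0.12 without wildtype pool 1, −0.66 without wildtype pool 3, −0.93 without knockout pool 1 and −0.08 without knockout pool 3. That of Pax6 was −0.39 without knockout pool 2.

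Cell cycle genes were lower as a list with the preset correlation. Of 46 tested members, 31 had lower and 15 higher means (median −0.24, camera adjusted p = 0.00617), and the adjusted p was 0.360 with an estimated correlation. Within numbers 1, 2 and 3 the median was −0.14, −0.24 and −0.29. Mcm2, of the replicative helicase, had 1228 ± 615 and 491 ± 118 in wildtype and knockout (SD, n = 3; log2 difference −1.16, SE 0.39), while its other probe set had a log2 difference of −0.0875. Rrm2, of ribonucleotide reductase, had 7535 ± 597 and 4965 ± 1489 (−0.64, SE 0.33), with −0.0155 for its other probe set. Ccne2, a cyclin E gene, had 781 ± 111 and 443 ± 160 (−0.82, SE 0.32). Without knockout pool 1 the difference was −0.40 for Rrm2 and −0.51 for Ccne2. Leaving out knockout pool 3 ended the call (adjusted p = 0.0703), as did leaving out both pools numbered 2, an alternative chosen after seeing the data (0.0535).

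Markers of other cell types of the gland and its surroundings made up the 4 lists called higher with the preset correlation. Macrophage, microglia and leukocyte markers had higher means for 19 of 20 tested members (median 0.38, camera adjusted p = 0.00164, 0.346 with an estimated correlation). Their median was 0.69, 0.21 and 0.32 within numbers 1, 2 and 3, and knockout pool 1 had the highest list median, 0.58 relative to the 6 arrays against 0.03 and 0.05 in knockout pools 2 and 3. With the preset correlation the adjusted p lay between 0.00176 and 0.0315 when 1 pool was left out, the highest being that without knockout pool 1. Cd163, a scavenger receptor gene of macrophages, had 540 ± 213 in wildtype and 1157 ± 457 in knockout (SD, n = 3; log2 difference 1.02, SE 0.39), the platelet factor gene Pf4 2219 ± 638 and 3821 ± 731 (0.80, SE 0.34), and Csf1r, the receptor gene for colony stimulating factor 1, 2041 ± 311 and 3087 ± 757 (0.57, SE 0.31). The other Csf1r probe sets had log2 differences of 0.28 and 0.0225. Spi1, a transcription factor gene of myeloid cells, had 159 ± 23.5 and 242 ± 13.9 (0.51, SE 0.27).

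Pericyte and smooth muscle markers had higher means for 11 of 11 tested members (median 0.38, camera adjusted p = 0.00793, 0.360 with an estimated correlation), with medians of 0.10, 0.37 and 0.85 within the 3 numbers. Acta2, the smooth muscle actin gene, had 2825 ± 585 in wildtype and 4357 ± 310 in knockout (SD, n = 3; log2 difference 0.64, SE 0.30), and Notch3, which the Notch list also holds, 1204 ± 107 and 1875 ± 406 (0.60, SE 0.29). Meningeal fibroblast and connective tissue markers had higher means for 21 of 25 (median 0.19, camera adjusted p = 0.0281, 0.346 with an estimated correlation), with medians of 0.12, 0.19 and 0.46. Col6a2, a collagen VI gene, had 1599 ± 659 and 2749 ± 185 (0.86, SE 0.38, with 0.54 for its other probe set), and Mgp, the matrix Gla protein gene, 3697 ± 880 and 6564 ± 3076 (0.75, SE 0.39). The Col6a2 difference was 0.46 without wildtype pool 3, and that of Mgp 0.40 without knockout pool 1. Crabp2 of the same list had a lower mean, with a log2 difference of −1.28 (SE 0.76), but was higher in knockout within number 1 (0.65, −1.65 and −2.84 within numbers 1, 2 and 3). Its difference was −2.32 without knockout pool 1 and −0.54 without knockout pool 3. Schwann cell and oligodendrocyte markers had higher means for 10 of 11 (median 0.28, camera adjusted p = 0.0336, 0.346 with an estimated correlation), with medians of 0.01, 0.36 and 0.20. Foxd3, a factor of neural crest cells, had 58.6 ± 34.8 and 192 ± 38.2 (1.31, SE 0.41, and 0.84 with an offset at the 40th percentile), the myelin gene Mbp 197 ± 36.7 and 299.5 ± 47.4 (0.52, SE 0.27), and Pdgfra, which the fibroblast list also holds, 1911 ± 72.5 and 3721 ± 1874 (0.81, SE 0.41). The Pdgfra difference was 1.23 without knockout pool 1 and 0.45 without knockout pool 3. Without wildtype pool 3 the adjusted p was 0.209 for pericyte, 0.209 for fibroblast and 0.0943 for Schwann cell markers, and without knockout pool 2 it was 0.114, 0.114 and 0.182. The fibroblast and Schwann cell calls also ended without knockout pool 3 (0.182 and 0.133), and the latter without wildtype pool 1 (0.153).

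**Figure D3:**
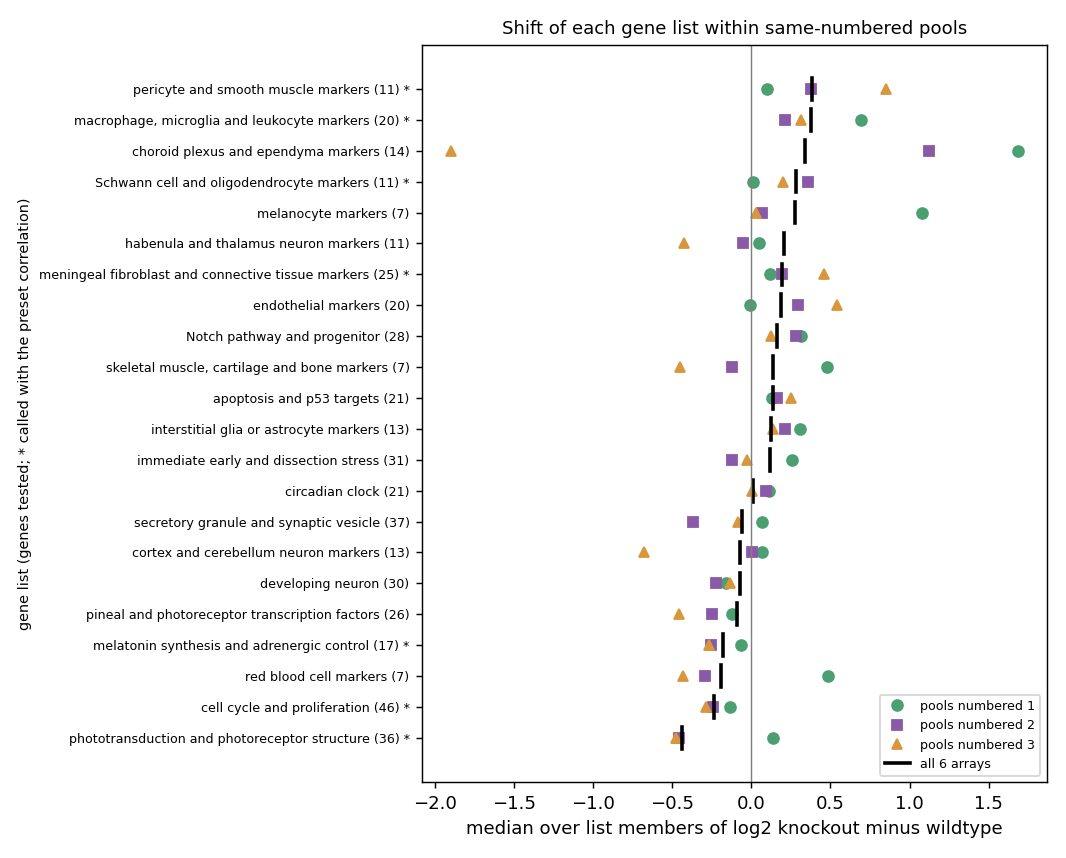
Each row is 1 of the 22 gene lists, with the number of genes tested, and the horizontal axis is the median over members of the log2 difference of knockout minus wildtype, as circles, squares and triangles within pools numbered 1, 2 and 3 and as a bar over all 6 arrays. The phototransduction list lies at 0.14 in number 1 and at −0.46 and −0.48 in the others, macrophage markers lie above 0 in all 3 numbers, and choroid plexus markers spread from −1.90 to 1.69.

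The other 14 lists were not called by camera with the preset correlation. Melanocyte (adjusted p = 0.0737), endothelial (0.0737), Notch and progenitor (0.0737), and apoptosis and p53 target genes (0.0999) had medians of 0.28, 0.19, 0.16 and 0.14, and developing neuron genes (0.0737) a median of −0.07. Robo4, an endothelial receptor gene, had 165 ± 20.5 in wildtype and 297 ± 19.0 in knockout (SD, n = 3; log2 difference 0.72, SE 0.26). Map2 and Elavl2, genes of neuronal microtubules and RNA binding, had log2 differences of −1.11 (SE 0.39) and −0.78 (SE 0.27). The other probe sets gave −0.81 and 0.0454 for Map2, and −0.38, −0.24, −0.15 and −0.0517 for Elavl2. Interstitial glia or astrocyte genes had an adjusted p of 0.170, choroid plexus and ependyma 0.244, circadian clock 0.342, cortex and cerebellum neurons 0.351, skeletal muscle, cartilage and bone 0.351, secretory granule and synaptic vesicle 0.464, red blood cell 0.487, immediate early and dissection stress 0.494, and habenula and thalamus neurons 0.944. Among clock genes, Npas2 had 87.8 ± 43.7 and 295 ± 130.2 (SD, n = 3; log2 difference 1.38, SE 0.41), while the list median was 0.01. Fos, induced by neuronal activity and by dissection, had 5873 ± 2723 and 3346 ± 2467 (−0.97, SE 0.55), with −0.62 without wildtype pool 1, −1.53 without knockout pool 1 and −0.48 without knockout pool 2. Within numbers 1, 2 and 3 the Fos difference was −0.55, −1.47 and −0.88, and with the number as a block its SE was 0.27 (limma adjusted p 0.768). En2, a homeobox gene of midbrain and cerebellum, had 2088 ± 1134 and 553 ± 263 (−1.85, SE 0.48). Within numbers 1, 2 and 3 the En2 difference was −3.57, −1.08 and −0.89, and without both pools numbered 1, an alternative chosen after seeing the data, it was −0.98. Its p adjusted over the list alone, 0.0506, was the smallest for any member of the 22 lists. With the preset correlation, leaving out 1 pool added calls for endothelial markers (adjusted p = 0.00580 without wildtype pool 1 and 0.0291 without knockout pool 1), Notch genes (0.0359 without wildtype pool 1), developing neuron genes (0.0460 without wildtype pool 2) and choroid plexus markers (0.00698 without wildtype pool 3 and 0.000124 without knockout pool 3). Quantile normalization added endothelial (0.0408) and developing neuron genes (0.0481), and no filter added melanocyte (0.0331) and developing neuron genes (0.0331). Over all arrays and with an estimated correlation the adjusted p of these 5 lists lay between 0.346 and 0.754.

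Over the 22 lists, 0 members passed the threshold in either direction, over all genes tested or adjusted over the list alone. Of the 100 named genes, 5 of them added after their values were seen, 39 had several tested probe sets, and for 25 of them at least 1 other probe set had the opposite sign (8 genes) or less than 2/3 of the printed difference. Of the 7 lists called with the preset correlation, 0 were called with an estimated correlation (smallest adjusted p = 0.346) and 0 by fry (smallest adjusted p = 0.225). The loss of calls with an estimated correlation is not by itself a sign of correlated members, since p also rose for lists with estimates under the preset 0.01.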

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

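Leaving out both pools numbered 2 or both pools numbered 1, and the block together with an estimated correlation, were alternatives chosen after the data had been seen, and all others were planned. Neurod1 kept its direction under all alternatives run. Without an offset its log2 difference was −4.87, with 0 genes lower, because its adjusted p became 0.0683. Leaving out 1 pool at a time gave between 0 and 1 lower genes and a Neurod1 difference between −5.04 and −4.13, with fewer samples in the fit. Without both pools numbered 2 it was −4.98 (adjusted p 0.201) and without both numbered 1 it was −4.80 (0.813), with 0 lower genes each time. Over all these alternatives the adjusted p of Neurod1 lay between 3.45e-05 and 0.813. Testing every probe set called 2 lower, both of Neurod1. At an unadjusted p under 0.05 and at least 2-fold, 83 genes were higher and 46 lower. Array weights called 1512 higher and 1420 lower genes, with a warning that the weights had not converged, and the pools numbered 2 weighed 7.05 and 6.20 against 0.204 to 0.541 for the rest, so that this fit rests mostly on 2 arrays. With the replicate number as a block the pairing left 1 lower and 0 higher genes, called 8 lists in place of 7 and changed no call except that of the pineal transcription factor list (adjusted p 0.0465 against 0.0525). With the block and an estimated correlation 0 lists were called, and the adjusted p was 0.452 for each of the 7 lists and for the pineal transcription factors. Lists as unlike as melanocyte and endothelial markers had this same adjusted p. The block leaves fewer residual degrees of freedom than the 4 of the fit without it. This setting is therefore a weak test, and its 0 calls decide little.

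Of 1398 alternative values for 100 genes (95 named by the rule and 5 added after their values were seen), 1394 kept their direction. The reversals were Tspan33 (−0.0239 without both pools numbered 1), Tyr (−0.26 with array weights and −0.14 without both pools numbered 1) and Myog (between −1.16 and 0.0432 when 1 pool was left out), and the cause was not tested.

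The number of called lists was 0 with an estimated correlation and 0 with fry, between 3 and 9 when 1 pool was left out, with 3 without knockout pool 2 or knockout pool 3, and 2 without both pools numbered 2. With an estimated correlation and with fry, adjusted p was 0.411 and 0.480 for phototransduction, 0.346 and 0.225 for macrophage, 0.360 and 0.414 for cell cycle, 0.360 and 0.253 for pericyte, 0.411 and 0.426 for melatonin, 0.346 and 0.225 for meningeal fibroblast, and 0.346 and 0.225 for Schwann cell genes. The estimated correlation between members was 0.31 for phototransduction, 0.20 for melatonin and 0.18 for pericyte genes, and between 0.02 and 0.09 for the other 4, against the preset 0.01. For pineal transcription factors it was 0.0078, yet the unadjusted camera p rose from 0.0191 with the preset to 0.0746 with the estimate. For Notch genes it was −0.016, and p rose from 0.0372 to 0.0787. A higher correlation is therefore not the whole of the difference between both settings. Without both pools numbered 2 the adjusted p was 0.0535 for cell cycle, 0.0573 for pericyte, 0.101 for melatonin, 0.0639 for fibroblast and 0.123 for Schwann cell genes. Without both pools numbered 1 every list called with all arrays stayed called. Pineal transcription factors (adjusted p 0.0263) and endothelial markers (0.00242) were added there. Without a filter it was 0.0569 for melatonin, 0.0569 for fibroblast and 0.0644 for Schwann cell genes, quantile normalization gave 0.0634 for fibroblast and 0.0634 for Schwann cell genes, and no offset gave 0.112 for Schwann cell genes. The causes of these changes were not tested. Leaving out 1 pool moved the adjusted p from 4.78e-07 to 0.0827 for phototransduction, 0.00583 to 0.0703 for cell cycle, 0.00176 to 0.209 for pericyte, 0.00698 to 0.129 for melatonin, 0.0176 to 0.209 for fibroblast and 0.00616 to 0.182 for Schwann cell genes.

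Lists that were not called turned direction in places, and the cause was not tested. Without both pools numbered 2 this held for choroid plexus (adjusted p 0.885), secretory (0.926) and red blood cell genes (0.927). Without both numbered 1 it held for choroid plexus (0.103), muscle and bone (0.943), immediate early (0.943) and habenula genes (0.851), and habenula genes also turned with quantile normalization (0.844) and no offset (0.965). Directions also turned without wildtype pool 1 (choroid plexus and habenula), wildtype pool 2 (habenula), wildtype pool 3 (immediate early), knockout pool 1 (choroid plexus and immediate early) and knockout pool 2 (secretory and red blood cell). Over all pools left out in turn, the adjusted p of these lists ranged from 0.000124 to 0.972 for choroid plexus, 0.190 to 0.988 for secretory, 0.0946 to 0.962 for red blood cell, 0.0845 to 0.772 for immediate early and 0.533 to 0.969 for habenula genes. In simulations with independent noise at this size 9.6% of genes changed by 1 on the log2 scale were recovered. Differences of that size therefore mostly lie under what 3 arrays per group call. Larger differences also went uncalled, such as −1.85 for Trim36 and −2.10 for Nat1.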

Other observations

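The tests on spermatid genes other than that of testis somatic genes in the lower pool, those on choroid plexus markers, on deviations shared by pool number and on ribosomal genes against genotype and amplification, and that on the genes beside Neurod1 were chosen after the results had been seen.

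Below Neurod1, the 5 genes with the smallest p among those with lower values were Trim36, Nat1, Rnd3, Trhde and Slc35b2, chosen after their values were seen. None passed (limma adjusted p = 0.998 each). The groups did not overlap for any of these 5, which alone makes each lower in knockout within all 3 pool numbers. Trim36, a ubiquitin ligase gene, had signals of 2502 ± 522 in wildtype and 664 ± 154 in knockout (SD, n = 3), a log2 difference of −1.85 (SE 0.30), while its other probe set had −0.36. Nat1, an arylamine N-acetyltransferase gene, had 282 ± 40.5 and 37.9 ± 23.0 (−2.10, SE 0.36), and Rnd3 had 5318 ± 786 and 1930.5 ± 568 (−1.47, SE 0.32). The Nat1 signals of 22.1, 64.3 and 27.4 in knockout pools 1, 2 and 3 lie around the 20th percentile of these arrays (44.1, 41.1 and 41.7). The size of its difference is therefore set by the offset, and was −1.40 with an offset at the 40th percentile. Trhde, the gene of the enzyme that degrades thyrotropin-releasing hormone, had 670 ± 323 and 195 ± 20.6 (−1.52, SE 0.33). Slc35b2, a Golgi transporter gene, had 274 ± 24.8 and 95.8 ± 37.2 (−1.25, SE 0.32).

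Of the sex-linked list, 4 members were tested and 0 passed. Eif2s3y, Kdm5d and Uty were low in wildtype pool 2 (22.5, 21.6 and 4.7) and knockout pool 1 (75.2, 21.4 and 11.0) and had signals of at least 1216, 328 and 210 in the other pools. Xist was present in all 6 arrays, at 27599 to 84474 and highest in knockout pool 1. Cga, the gene of the pituitary glycoprotein hormone alpha chain, had a signal of 1278 in knockout pool 1 and between 82.5 and 225 elsewhere. Cga, like the marker genes named for single pools in what follows, was chosen after its values were seen.

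Spermatid transcripts were high in both pools numbered 2: of 48 listed genes, 24 exceeded 500 in knockout pool 2, and their median was 1525 there, 338 in wildtype pool 2 and 32.2 to 83.7 elsewhere, with Fabp9 at 35627 and 5685 and Crisp2 at 17677 and 1700. Male glands and loss of Neurod1 are argued against: wildtype pool 2 had the second highest spermatid median but rank 2 from below of 6 in Y-linked level, and the lowest knockout pool lay −2.02 on the log2 scale from the highest wildtype pool. Germ cell RNA carried into these pools is a candidate explanation. Of the 24 genes, 17 were listed after their values had been seen. Of the 7 others, 6 (85.7%) were also higher in both pools than in each other array. Chance gives 20% for exchangeable arrays once knockout pool 2 is high by selection. Same-numbered pools share deviations, so the share is not read against 20%. Of the 24 genes, 10 lay above the filter signal of 105 in their mean over the other 4 arrays, and 3 in each of these. Whether whole testis was the source stays open: 8 testis somatic genes had a median shift of −0.024 in the lower of both pools, where their baseline signal of 295, near the spermatid median of wildtype pool 2, would hide such a share, and of 0.145 in knockout pool 2, below the bound of 0.25 set against it by less than the SD of 0.30 over genes, although their median signal of 332 there lay within the 215 to 353 of the other arrays. The Leydig gene Cyp17a1 had 24.1 in knockout pool 2, against 37.7 and 44.9 in knockout pools 1 and 3 and 12.6 to 15.1 in the wildtype pools. All these signals lie far under the filter signal of 105, so they decide nothing. Whether 1 source was diluted in the wildtype pool also stays open, since the log2 ratio between both pools (median 2.80) had an SD of 0.80, between the bounds set for and against it. In knockout pool 2 the spermatid genes Prm2, Tnp2 and Smcp reached 580, 327 and 51.9, and Prm1, Tnp1 and Odf1 reached 3856, 4433 and 1585. Signals of different probe sets are not comparable as amounts, so nothing is concluded from these levels.

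Choroid plexus transcripts differed between pools of the same genotype. Kcne2, Kcnj13 and Sostdc1 had signals of 74.1, 174 and 128 in wildtype pool 1 and 184, 154 and 108 in knockout pool 3, where Ttr was lowest, against 2964, 1405 and 2539 in wildtype pool 3 and 348, 407 and 443 in wildtype pool 2, where Ttr was 38903. Loss of Neurod1 as the cause is argued against, since the lowest knockout pool had −6.39 on the log2 scale relative to the highest wildtype pool for Ttr. Choroid plexus tissue taken with some glands is a candidate explanation: 8 of the 13 other tested markers on this list, fixed before the data were examined, had the same 2 lowest pools as Ttr, 61.5%. Chance gives 6.67% for exchangeable arrays and independent markers. The members of this list vary together, with an estimated correlation of 0.70, so the share is not read against that figure. It also cannot tell carried tissue apart from another cause that moves these markers together. Of the 13, 8 had signals above the filter in both of these pools as well, with Clic6 at 1361 and Calml4 at 2869 in wildtype pool 1.

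Knockout pool 1 stood apart from the other knockout pools. Over 213 ribosomal and respiratory chain genes its median was 1.00 above the mean of the 6 arrays, against −0.30 and −0.60 in knockout pools 2 and 3. Loss of Neurod1 as the cause is argued against, since the lowest knockout median lay below the lowest wildtype median by a difference of −0.37. Uneven amplification or degradation of the RNA could raise short abundant transcripts, but it cannot be told apart from other sources, because transcript lengths and control probe sets were not used here. With the preset correlation the macrophage list had an adjusted p of 0.00164 with this pool and 0.0315 without it (0.346 with all arrays and an estimated correlation), and without it 9.07% of genes had an unadjusted p under 0.05, against 3.34% with all arrays.

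The lowest correlation across genes of deviations within a pool number was 0.253, the value tested for a shared day. Of the 50 tested genes nearest to Neurod1 on its chromosome, 2 (Ttn and Itga4, named after their values were seen) had an unadjusted p under 0.05, where runs of 50 neighbouring genes had a median of 2 and 50.1% of them at least as many. The log2 difference was −1.82 (SE 0.69) for Itga4 and 1.25 (SE 0.55) for Ttn. A count over 50 genes cannot show a change limited to a few of them.

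The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For lower genes 1 split gave as many, the real one with 1 gene against at most 0 in the others, for higher genes all 10 did (0 in the real one and at most 0 in the others), and for called lists 1 did, the real one with 7 against at most 6. The 3 other splits that part every same-numbered pair gave 5, 2 and 0 lists, and 289, 428 and 108 genes at an unadjusted p under 0.05, against 428 in the real one. The 6 remaining splits keep a same-numbered pair on each side, and that of wildtype pools 1 and 2 with knockout pool 1 against the rest gave 2407 such genes, which points to a structure of the samples other than genotype.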
